A study of Homo sapiens with 2 samples.

How the data were processed

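Total RNA from 2 human samples, the ovarian carcinoma line UWB1.289 and its partner with BRCA1, was sequenced after ribosomal RNA depletion as strand-specific dUTP libraries, per the labels' protocols. The genotype labels name one sample a BRCA1 knockout and the other wild type, and these labels set the groups, with 1 sample in each.

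The table of differential genes holds 4 kinds of value. FPKM, a fragment count scaled to transcript length and library size, is given as a mean per line by the authors. Every deposited FPKM was, within a tolerance of 0.02, a whole number of steps of its last decimal after multiplication by 3, so each was taken as a mean of 3 values, although the labels describe 1 sample per line. The log2 fold change (deficient over BRCA1-expressing), the p-value and the adjusted p-value are the authors' own, per the file headers, and the test that gave them is not given in the sources used here. The adjusted p-values follow a Benjamini-Hochberg correction over 38868 features. The last listed gene has rank 2716 in it, so the 1806 genes listed are part of those that passed 0.05. HISAT2 and StringTie 1.3.3b are named in the submitters' processing notes, which also name the mouse build mm9. The table has human Ensembl IDs, and all 1799 IDs matched in GENCODE release 29 (GRCh38) overlap their gene at the coordinates given, so these are read as GRCh38. A table of selected genes can show neither what stayed the same nor the depth of a library. FPKM of overlapping genes and near-identical copies depends on how reads were assigned, and depletion of ribosomal RNA keeps small and mitochondrial RNAs that can enter a longer gene's value.

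Of the listed genes, 47 were at 0 FPKM in the deficient line and 55 in the other, and 501 were under 1 FPKM in both. Such genes are given no fold where one line is listed at 0. Across the 1704 genes above 0 in both, the log2 FPKM ratio and the authors' log2 fold change had a Pearson r of 0.991 (across genes, which are not replicates). They differed in sign for 1 gene, ACTR6. There were 3 symbols stored as dates, which were restored through their gene IDs (MARCHF3, MARCHF4 and MARCHF10), and 6 assembled loci without a gene ID.

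With means only, no test across samples was possible, and the design fixed before the data were examined, written for 1 library per group, has none. The difference of a gene is log2 of FPKM + 1, deficient minus BRCA1-expressing, and a size rule of 2-fold gave the counts. For each of 27 gene lists fixed before the data were examined, the higher and lower members were counted. List sizes count names, so a gene under both an older and a newer symbol can count more than once. For lists with at least 5 members in the table, the median difference was given as a percentile among 10000 random lists of the same size, drawn from the listed genes within 10 bins of mean expression. It says whether a list median lies further out than that of other called genes, and is no p-value. Both the size and the direction of the differences move the median, so a high percentile need not mean a lean in direction. Genes named are BRCA1 and the FAM3 family, the 12 largest differences in each direction among named genes at 5 FPKM or more in the higher line, choline list members at 1 FPKM or more in either line, and up to 6 members of each other list with the largest difference at 1 FPKM or more. Some genes that this rule selects are not reported here. Transcript GC content and length were taken from the longest GENCODE transcript of 1796 genes.

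For the order of genes along chromosomes 1 to 22 and X, directions were shuffled 1000 times within 20 bins of GC content. A first rule for same-direction blocks, longer than the longest block in any shuffle, gave 0 blocks. It was then replaced by a score that weighs each gene by how rare its direction is in its GC bin, with a threshold at the 95th percentile of the highest score per shuffle, which gave 3 blocks. By then the number of called genes on each chromosome had been seen. The methods were tested on simulated data. For the lists, run on 1806 genes, 25 of 400 random lists of 16 genes fell outside the central 95%, and 162 of 400 lists with 14 higher and 2 lower genes were above the central 95%. For the block score, run on 1795 genes, 7 of 100 shuffled data sets gave a block and a planted block of 40 genes was found in 100 of 100.

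Alternatives were pseudocounts of 0.1 and 0.01, equal totals, centring, minimum FPKM of 1 in either or both lines, a 4-fold rule, a stricter threshold on the authors' table and unmatched random lists. Matching on GC content or length, leaving out the blocks and using the authors' fold for the lists were added after seeing the data. Matching on GC content or length together with expression used 5 bins for each property, a coarser expression match than the 10 bins above. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.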

Results

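RNA was sequenced from a pair of human ovarian cancer lines that differ in BRCA1. UWB1.289 is an established line from a serous ovarian carcinoma that lacks functional BRCA1, the tumour suppressor needed for DNA repair by homologous recombination, and its partner is the same line with BRCA1 supplied. The labels give 1 sample for each, untreated, as ribosomal RNA-depleted and strand-specific libraries of total RNA. The series title sets the question: how choline metabolism and the secreted protein FAM3C relate to metastasis of BRCA1-deficient ovarian cancer. The values used here are a table of 1806 genes that the authors called different between the lines, with a mean FPKM per line. Total read counts per library were not used here, so the depth is unknown. The values behind the means were not used here, so no spread or n is given for any FPKM below. Differences are given as the log2 ratio of FPKM + 1, BRCA1-deficient over BRCA1-expressing, which understates the change of low genes.

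BRCA1 itself was lower in the BRCA1-deficient line. BRCA1 (ENSG00000012048, chromosome 17, 43044295 to 43170403, minus strand, GRCh38) had a mean of 5.63 FPKM in the deficient line and 22.03 FPKM in the line with BRCA1, a log2 difference of -1.80. In the authors' deposited table its log2 fold change was -2.89 with an adjusted p of 3.09e-07. Of the 25 genes in the list of BRCA1, its partners and homologous recombination, 2 had a row, both lower: the other was RAD51AP1, a recombination accessory protein, at 9.80 against 26.1 FPKM. The remaining 23 were not analysed here.

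Genes differed in both directions, from collagen and Wnt pathway genes to chemokine receptors. REC8, a meiotic cohesin subunit, had 47.6 FPKM in the deficient line against 2.41, COL6A1, a type VI collagen chain, 33.6 against 1.91, and DKK1, a secreted Wnt antagonist, 59.6 against 5.44. In the other direction, NPR3, the clearance receptor for natriuretic peptides, had 0.0716 FPKM against 17.2, ADAMTS12, a secreted metalloprotease, 3.15 against 44.1, and COL1A2, a type I collagen chain, 10.5 against 97.3. CXCR4, a chemokine receptor, was at 0.599 against 9.42 FPKM. The authors' deposited table gave log2 fold changes of 4.55 for REC8, 4.27 for COL6A1, 3.49 for DKK1, -7.23 for NPR3, -4.11 for ADAMTS12, -3.02 for COL1A2 and -3.86 for CXCR4, with adjusted p between 2.12e-35 for NPR3 and 5.75e-09 for COL1A2.

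By the sign of the fold in the authors' deposited table, 967 of the 1806 genes were higher in the deficient line and 839 lower, and all had an adjusted p of at most 0.0499. By that fold, 1795 of the genes differed at least 2-fold. On the scale of FPKM + 1, which shrinks the change of low genes, 457 genes were at least 2-fold higher and 406 at least 2-fold lower. Rescaling moved the split, but both rescalings are computed from called genes alone, so part of the move follows from that selection and it does not show how the libraries should be scaled. With both columns brought to equal totals over the listed genes (a log2 shift of -0.43 for the deficient line) the split was 178 higher and 520 lower. Centred on the median ratio of genes at 1 FPKM or more in both lines, which moved the deficient line down by 1.01 on the log2 scale and the median difference of all listed genes by -0.21, it was 63 higher and 550 lower. The test behind the adjusted p-values is not given in the sources used here, and any spread they rest on may be technical, since the labels do not name separate cultures.

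**Figure D1:**
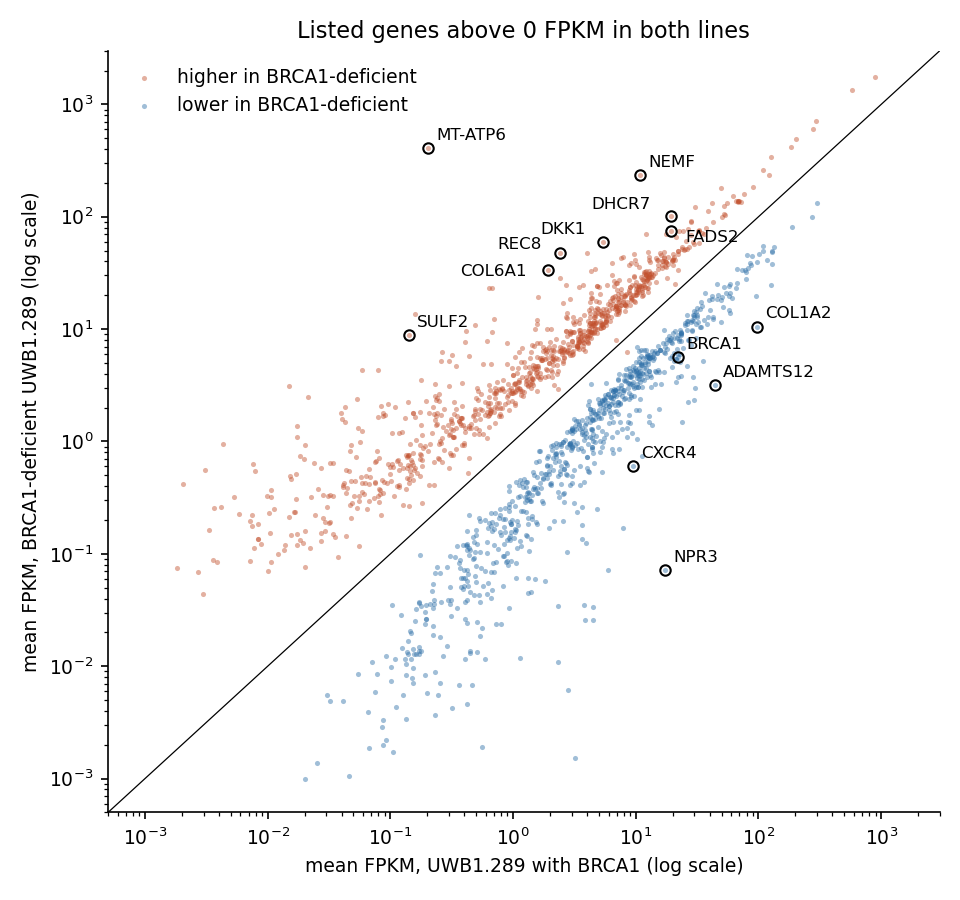
Mean FPKM of each gene in the BRCA1-deficient line (vertical, log scale) against the line with BRCA1 (horizontal, log scale), for the 1704 listed genes above 0 in both. Each point is a gene, the diagonal marks equal FPKM, and circled genes include BRCA1 at 5.63 against 22.03 FPKM and NPR3 at 0.0716 against 17.2 FPKM.

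Further genes with the largest differences at 5 FPKM or more were EEF1A2, a translation elongation factor, at 13.6 FPKM in the deficient line against 0.159, SULF2, an extracellular heparan sulfatase, at 8.79 against 0.141, EHF, an epithelial transcription factor, at 28.8 against 2.42, MYL2, a myosin light chain, at 23.2 against 0.676, HIST1H4F at 47.1 against 4.01, and S100A9, a calcium-binding protein of inflammation, at 10.9 against 0.493. DEFB4A, a beta-defensin, had 23.1 against 0.636 FPKM, but reads of its near-identical copy DEFB4B could be counted to either gene. Lower genes included KCNIP1 at 1.48 against 23.9 FPKM, ABCA4 at 2.34 against 30.03, TMEM178A at 2.23 against 26.4, NXPH2 at 0.169 against 7.90, the scavenging chemokine receptor ACKR2 at 0.737 against 11.2, and MAP1LC3C at 0.0724 against 5.94. PASD1 was listed at 0 in the deficient line and at 10.3 FPKM in the line with BRCA1. The 2 largest differences among higher genes, on the log2 scale of FPKM + 1, are uncertain. MT-ATP6 (407 against 0.204 FPKM, mitochondrial positions 8527 to 9207) overlaps MT-ATP8 and MT-CO3 on its strand and was the only 1 of 15 mitochondrially encoded genes with a row. NEMF (235 against 10.8 FPKM) spans the abundant small RNA genes RN7SL2 and RN7SL3 in the coordinates given, and the authors' deposited table gave it a log2 fold change of 2.24, well under the FPKM ratio.

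Genes of lipid and sterol synthesis were higher in the BRCA1-deficient line. Of the 38 list members, 16 had a row and 15 of those were higher. INSIG1, which holds the sterol-sensing complex in the endoplasmic reticulum, had 24.6 against 3.73 FPKM. DHCR7, the last enzyme of cholesterol synthesis, had 102 against 19.4 FPKM, and the fatty acid desaturase FADS2 74.2 against 19.4, although FADS2 overlaps FEN1 on its strand. The cholesterol exporter ABCG1 had 5.23 against 0.303 FPKM. PLIN2, which coats lipid droplets, was the single lower member, at 1.73 against 8.82 FPKM. Further higher members, named after their values were seen, were FASN at 112 against 38.9 FPKM, SCD at 131 against 41.6 and SREBF1 at 17.4 against 7.89. The authors' deposited table gave log2 fold changes of 3.11 for INSIG1, 2.22 for DHCR7 and -2.27 for PLIN2. The list median was 1.48, at the 99.98th percentile of 10000 random lists of called genes matched on expression. Its members had a median GC content of 54.4%, and against random lists matched on GC content and expression the percentile was again 99.98.

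**Figure D2:**
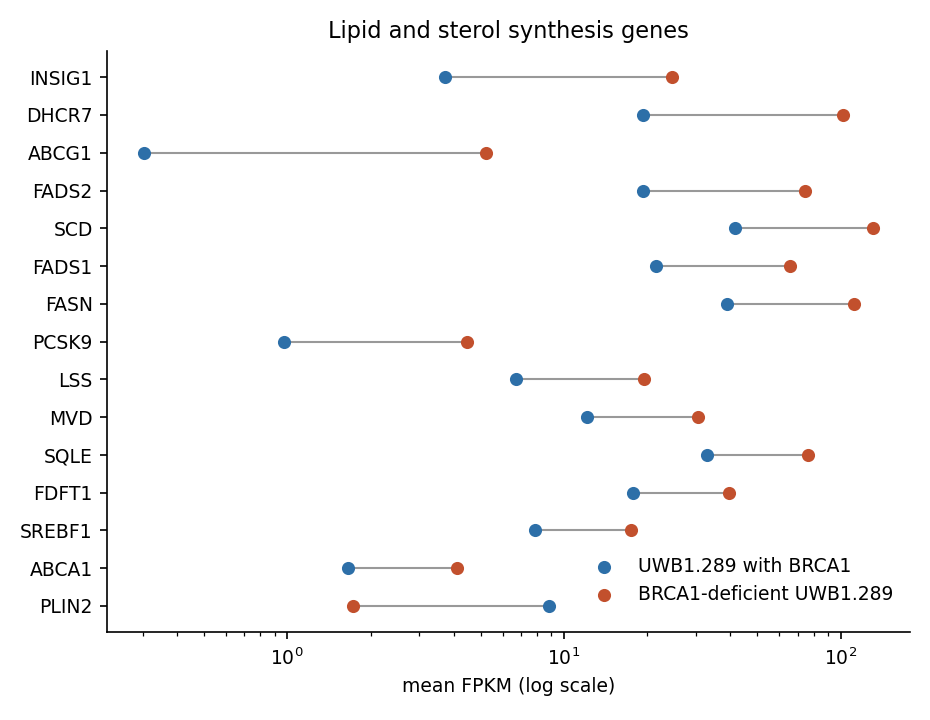
Mean FPKM (log scale) of the listed lipid and sterol synthesis genes reported here, in the line with BRCA1 (blue) and the BRCA1-deficient line (red), joined by a line per gene. The deficient line is to the right for each gene shown except PLIN2, where it is to the left (1.73 against 8.82 FPKM).

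Few genes of choline uptake and phosphatidylcholine metabolism were in the table, and they went both ways. Of the 50 list members 6 had a row, 2 higher and 4 lower in the deficient line. SGMS1, which makes sphingomyelin from phosphatidylcholine, had 6.13 against 20.4 FPKM, and ETNK1, an ethanolamine kinase, 7.89 against 23.6. LPCAT2, which acylates lysophosphatidylcholine, was higher at 3.62 against 1.65 FPKM. In the authors' deposited table SGMS1 had a log2 fold change of -1.59 (adjusted p 0.000255) and ETNK1 of -1.52 (0.00742), and LPCAT2 had an adjusted p of 0.0153. The other members stayed under 1 FPKM in both lines and are named after their values were seen: SLC44A4, a choline transporter-like protein, at 0.924 against 0.0202 FPKM, ENPP6 at 0.110 against 0.759 and SLC22A2 at 0.00789 against 0.151. In the authors' deposited table SLC44A4 had the smallest adjusted p of the list, 4.95e-14, with a log2 fold change of 6.80. Its log2 FPKM ratio departs from that fold by more than 1. In the same table ENPP6 and SLC22A2 had log2 fold changes of -2.32 and -3.60 (adjusted p 0.00098 and 0.0172). The list median was -0.43, at the 19.3rd percentile of random lists matched on expression and at the 69.9th when matched on GC content too, inside the central 95% either way. None of the 4 members of the FAM3 family, FAM3C included, had a row in the values used, so none is analysed here. In the list of one-carbon and methionine metabolism 1 of 22 genes had a row, NNMT, which methylates nicotinamide, at 23.4 against 65.1 FPKM.

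Mesenchymal and matrix genes were mostly higher in the deficient line. Of 30 genes in the mesenchymal and EMT list (EMT is epithelial to mesenchymal transition) 12 had a row, 10 higher and 2 lower. COL6A2 had 19.1 against 1.60 FPKM, the gelatinase MMP2 6.30 against 0.264, the transcription factor TWIST2 5.18 against 0.259 and THY1 17.8 against 4.75. The lower members were COL1A2 (10.5 against 97.3 FPKM) and FBN1, named after its values were seen, at 0.891 against 2.99. POSTN and PDGFRB, among the 10 higher, were listed at 0 in the line with BRCA1 and under 1 FPKM in the other. The list median of 1.24 lay at the 99.89th percentile of random lists matched on expression, and at the 99.5th when matched on GC content as well. The members had a median GC of 55.9%. In the GC quintile that holds this value, 80.2% of listed genes were higher. The count of 10 in 12 is close to that share, so the percentile reflects the size of the differences as well as their direction. Matrix proteases and their inhibitors had 10 of 32 genes in the table, 8 higher and 2 lower, with a median of 1.301 at the 99.67th percentile (99.1 with GC content). ADAMTS9 had 13.9 against 2.76 FPKM, ADAMTS1 11.5 against 3.05, PLAT, tissue plasminogen activator, 20.5 against 7.22, and ADAM8 5.66 against 1.58, while ADAMTS12 was the lower one above 5 FPKM. MMP2 belongs to both lists. In the epithelial adhesion and keratin list 1 of 30 genes had a row, the mucin MUC1, at 24.3 against 4.81 FPKM.

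IL1A, IL1B, CSF1 and CSF2, genes of secreted inflammatory signals, were higher in the deficient line, and CCL2 was lower. Of 33 inflammatory cytokines, chemokines and NF-kB targets 9 had a row, 8 of them higher. IL1B had 12.9 against 3.10 FPKM, IL1A 31.9 against 11.7, CSF2 23.5 against 8.93, CSF1 74.7 against 32.4 and SOD2 75.3 against 32.1. CCL2, a monocyte chemoattractant, had 12.9 against 39.0 FPKM. The list median of 1.18 was at the 94.4th percentile with random lists matched on expression, inside the central 95%, and at the 99.3rd when they were matched on GC content too. The members had a median GC of 45.7%. Interferon-stimulated genes split by gene: of 41 names, DDX58 and RIGI being 1 gene, 6 had a row, 2 higher and 4 lower. IFITM1 (26.8 against 6.64 FPKM) and IFITM2 (7.66 against 1.99) were higher, and GBP1 (8.25 against 31.1), HERC5 (2.59 against 6.59) and SAMD9L (0.423 against 1.65) were among the lower. IFITM1 and IFITM2 overlap on the same strand and can share reads. Their list median was -0.91, at the 15.2nd percentile. Antigen presentation had 7 of 24 genes in the table, 5 higher and 2 lower, with a median of 0.45 at the 65.2nd percentile. CD74 (42.0 against 20.05 FPKM) and HLA-F (5.21 against 2.53) were higher, and HLA-DMB (0.195 against 2.54) and HLA-DQB1 (0.607 against 3.48) lower.

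Genes of the growth factor list went both ways, with EPHB2, AXL and KDR among the higher and the binding proteins IGFBP5 and IGFBP7 among the lower. Of the 37 receptors, ligands and binding proteins in it 11 had a row, 7 higher and 4 lower. At 1 FPKM or more in either line 6 were higher, and the 2 lower were IGFBP5 and IGFBP7. KIT and PDGFRA, lower, and PDGFRB, higher, were under 1 FPKM in both lines and are named after their values were seen. EPHB2 had 37.2 against 8.78 FPKM, the receptor tyrosine kinase AXL 132 against 55.5, KDR 3.15 against 0.298 and the ligand AREG 29.8 against 12.5, while IGFBP7 had 24.5 against 127 and IGFBP5 19.9 against 95.5. The list median of 1.06 was at the 95.1st percentile. Of 46 genes in TGF-beta, BMP and Wnt signalling 11 had a row, 6 higher and 5 lower. WNT7A had 30.6 against 6.41 FPKM, WNT7B 9.72 against 3.46, WNT9A 3.52 against 0.823 and FSTL3, an activin antagonist, 22.4 against 6.98, and TGFBR3, a TGF-beta co-receptor, was lower at 2.59 against 9.13. The median of 1.20 was at the 99.5th percentile, but it did not stay outside the central 95% with a pseudocount of 0.1, where it was at the 86.6th. It is the smallest of the 6 higher values, that of SMAD3. The split of 6 higher and 5 lower is close to the 53.5% higher among all listed genes, so the percentile shows no lean in direction. The immediate early list has 27 names, with CYR61 and CTGF also listed as CCN1 and CCN2. In it 6 had a row, 4 higher and 2 lower, with a median of 1.09 at the 95.4th percentile. MYC (10.9 against 4.60 FPKM), FOSL1 (6.41 against 2.17), DUSP5 (51.6 against 23.6) and KLF2 (2.91 against 0.769) were higher and EGR1 (1.39 against 13.6) was lower.

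Markers of serous ovarian and Mullerian identity were divided, with 11 of 30 in the table, 5 higher and 6 lower, and a median of -0.06 at the 36.3rd percentile. The CA125 antigen gene MUC16 had 6.21 against 1.40 FPKM, the protease inhibitor SLPI 605 against 278, CD24 21.3 against 10.1 and LHX1 2.39 against 0.0530. CDH6, a cadherin, had 41.1 against 117 FPKM and the folate receptor FOLR1 2.80 against 6.56. Among p53 targets 5 of 26 had a row, with GADD45B (27.8 against 11.3 FPKM) and PLK3 (9.46 against 4.54) higher and PHLDA3 (0.318 against 2.39), RRM2B (6.12 against 14.8) and SESN1 (0.961 against 2.23) lower, and the median was -0.72 at the 34.1st percentile. Glycolysis and hypoxia had 5 of 33 genes in the table, 1 higher and 4 lower, with a median of -0.55 at the 16.1st percentile, or the 1.96th when random lists were matched on GC content. The median is the value of CA12 (0.206 against 0.766 FPKM), which like the lower member SLC2A3 was under 1 FPKM in both lines. Both were named after their values were seen. The hexokinase HK2 had 11.5 against 49.0 FPKM and ANGPTL4 8.28 against 21.8, while the lactate exporter SLC16A3 was higher at 16.6 against 5.94. Of 25 genes of the integrated stress response and amino acid transport 1 had a row, VLDLR, at 2.10 against 5.71 FPKM. The drug efflux and PARP inhibitor response list had 3 of 24, with ALDH1A3 (6.53 against 1.82 FPKM) and SCARF2 (7.74 against 3.40) higher. The lower 1 was ALDH1A1, under 1 FPKM in both lines. No ABC transporter or PARP gene of that list had a row. The histone list has 40 names, many of them older and newer names of the same gene. In it 2 had a row, H1F0 (43.8 against 16.9 FPKM) and HIST2H2BE (27.6 against 12.2), both higher. None of the 34 proliferation and mitosis genes had a row, so none is analysed here.

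Markers of other cell types gave no common direction. All 3 endothelial markers with a row, of 10, were higher, including EGFL7 at 26.0 against 7.03 FPKM and CDH5 at 13.4 against 4.64. All 3 fibroblast or stromal markers with a row, of 10, were lower, including COL1A2 and MFAP5 (0.515 against 2.71 FPKM), with PDGFRA listed at 0 in the deficient line. None of 10 leukocyte markers had a row. Of 20 neuronal and neuroendocrine genes 6 had a row, 1 higher and 5 lower, with a median of -1.03 at the 4.25th percentile. NCAM1 had 5.40 against 21.3 FPKM, MAP2 1.09 against 4.23, SNAP25 0.639 against 2.68 and NLGN1 0.512 against 1.81, and the tubulin gene TUBB3 42.9 against 14.7. Cancer-testis antigens had 6 of 27 genes in the table, all lower. DDX43 had 0.535 against 5.28 FPKM and SSX2 0.192 against 1.55, while the 4 MAGE-A genes were listed at 0 in the deficient line and under 1 FPKM in the other. The list median of -0.27 was at the 0.330th percentile when matched on expression in 10 bins. It was at the 28.5th when matched on GC content and expression in 5 bins each, and at the 29.2nd with unmatched lists. The expression match was coarser in both, so the move cannot be set down to GC content. Of the 27 lists, 15 had at least 5 genes in the table, and 5 of these lay outside the central 95% of random lists matched on expression. Centring left 891 of the listed genes higher and 915 lower in the deficient line and lowered the medians of several lists, to 0.55 for lipid and sterol synthesis, 0.32 for mesenchymal and EMT, 0.35 for matrix protease, 0.22 for TGF-beta, BMP and Wnt, 0.19 for inflammatory, 0.16 for immediate early, 0.06 for growth factor and 0.02 for antigen presentation genes, and further down to -1.43 for interferon-stimulated and -1.13 for p53 target genes.

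**Figure D3:**
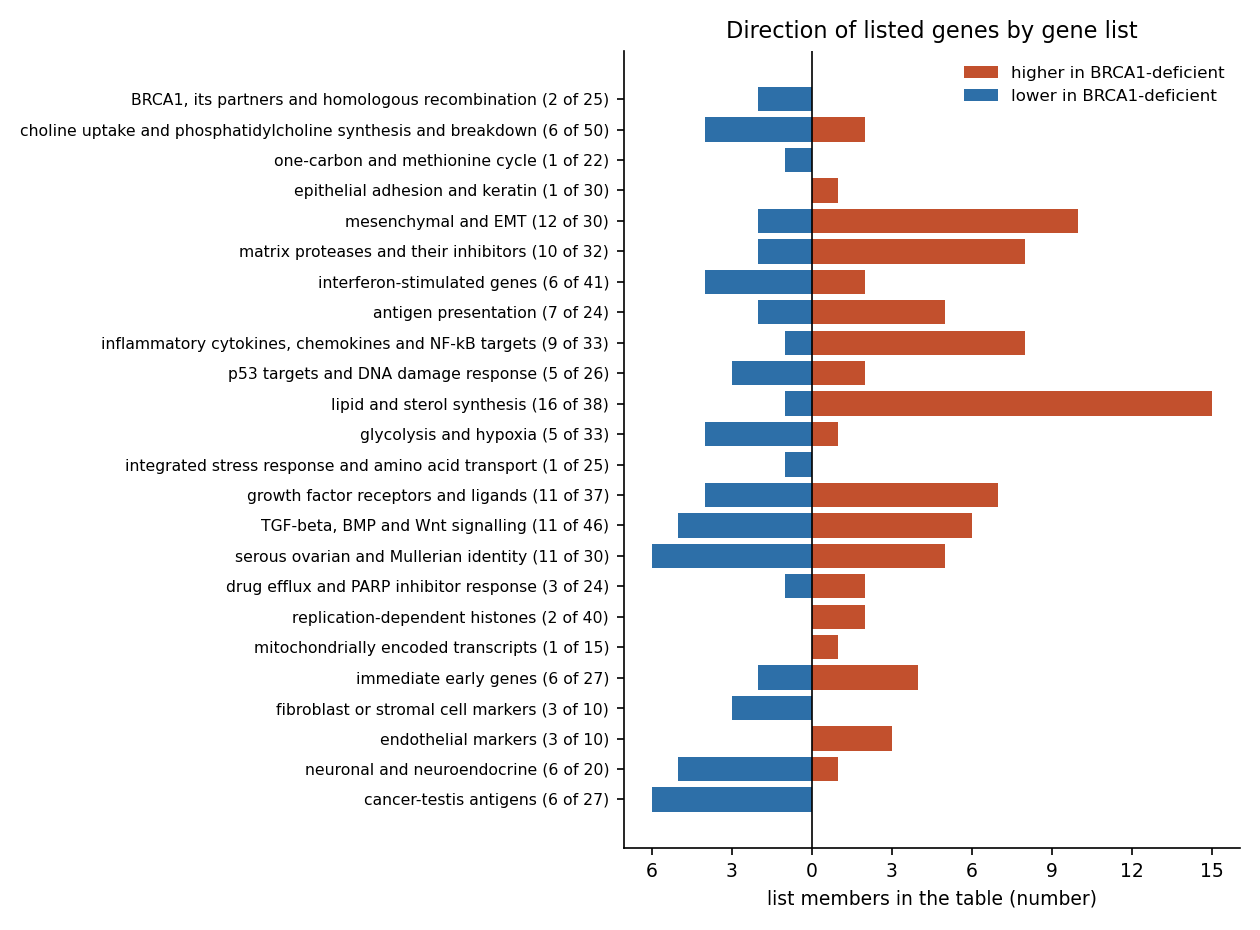
Number of listed genes higher (red, to the right) and lower (blue, to the left) in the BRCA1-deficient line for each gene list with a row, with the genes in the table and the list size in brackets. Lipid and sterol synthesis has 15 higher and 1 lower, and cancer-testis antigens 0 higher and 6 lower.

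The direction of change moved with the base composition and chromosomal place of the genes. Genes higher in the deficient line had a median transcript GC content of 58.0% and genes lower in it 44.1%. By quintile of GC content, from low to high, 14.2%, 24.0%, 59.3%, 80.2% and 89.7% of the genes were higher. Higher genes were also shorter, with a median transcript of 3188.5 bases against 4505.5. Along the chromosomes, 73.7% of neighbouring listed genes shared a direction, against a mean of 61.8% and at most 64.9% in 1000 shuffles of the directions among genes of like GC content. The 3 blocks are by definition runs of 1 direction, so their counts give their size and are no further evidence. On chromosome 9, from 1049858 to 78031458, all 52 listed genes were lower in the deficient line, among them JAK2, CD274 (PD-L1), MTAP and CDKN2B, named after their values were seen. PLIN2 and VLDLR, given above, also lie there. On chromosome 12, from 280129 to 20684381, all 33 were lower, RAD51AP1 and MFAP5 included. On chromosome 9 from 83242990 to 114806301 all 18 were higher.

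**Figure D4:**
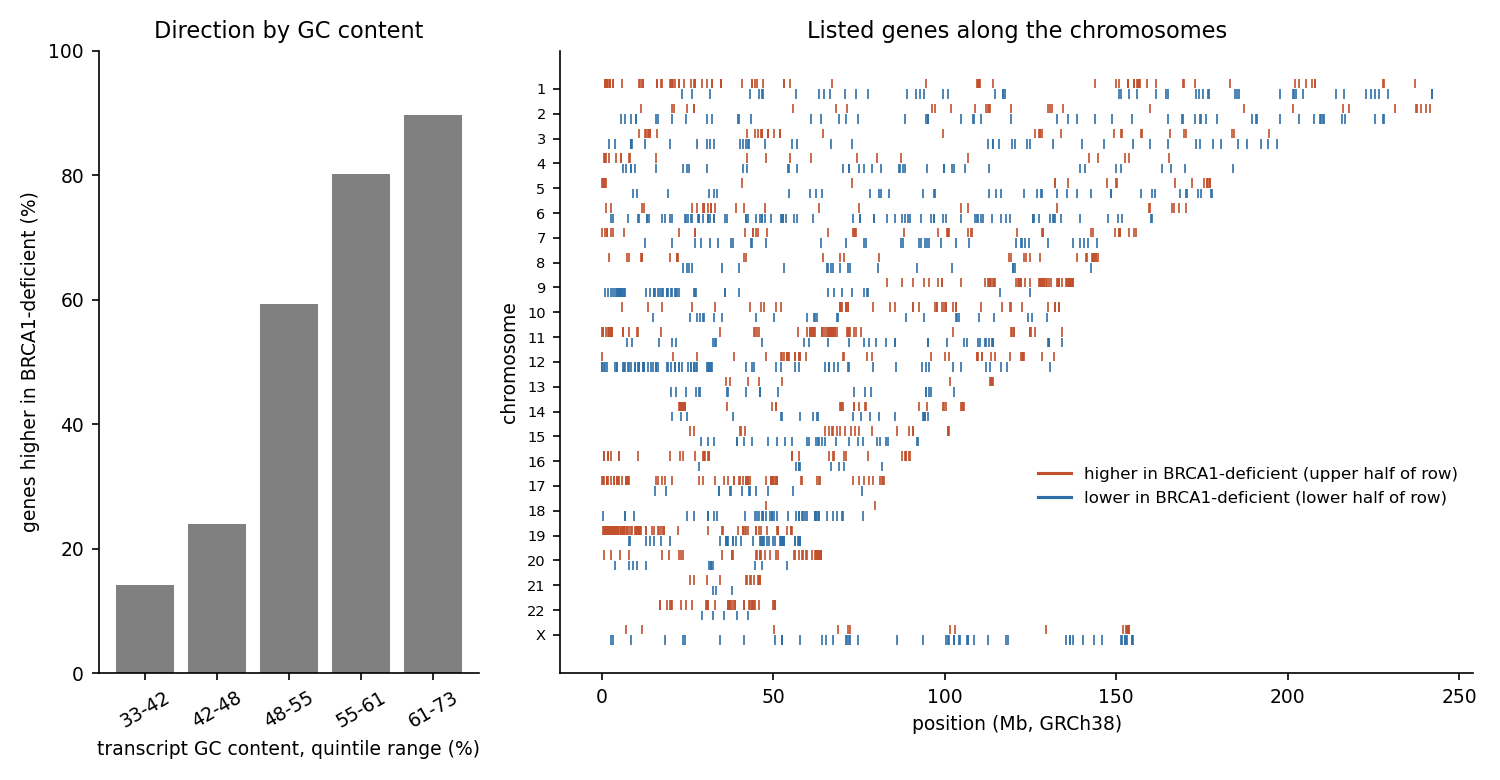
Left, percent of listed genes higher in the BRCA1-deficient line by quintile of transcript GC content, from 14.2% to 89.7%. Right, position of each listed gene along chromosomes 1 to 22 and X in megabases (GRCh38), higher genes in red above and lower genes in blue below, with a run of lower genes over the start of chromosome 9.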

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

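Matching on GC content or length, leaving out same-direction blocks and using the authors' fold for the lists were chosen after seeing the data. The medians of lipid and sterol synthesis, mesenchymal and EMT, and matrix protease genes stayed above the central 95% in each alternative run, although centring, which shifts the random lists too, lowered them to 0.55, 0.32 and 0.35. BRCA1 stayed at least 2-fold lower. Pseudocounts of 0.1 and 0.01 gave 840 and 896 higher and 756 and 812 lower genes, as a smaller pseudocount by construction shrinks low genes less. Equal totals gave 178 higher genes and centring 63, the 4-fold rule 50 higher and 42 lower. The stricter threshold left 313 higher and 290 lower genes of the authors' deposited table. TGF-beta, BMP and Wnt genes fell inside the central 95% with pseudocounts of 0.1 and 0.01 (medians 1.24 and 1.24), centring (0.22), 1 FPKM in both lines (1.26) and the authors' fold (1.43). Cancer-testis antigens (-0.27) did so with unmatched lists and with matching on GC content or length. Lists that moved outside it were inflammatory genes (1.18, unmatched or GC-matched), growth factor genes (1.06, unmatched), glycolysis and hypoxia (-0.55, GC-matched), and neuronal genes (-1.75 and -1.96 at pseudocounts of 0.1 and 0.01, -1.03 with length matching). The cause was not tested. Of the named genes other than BRCA1, 66 kept their side of the 2-fold rule under centring, 35 fell under it and 5 passed it, and under equal totals 81, 21 and 4. Those that fell under it with centring include IL1A, IL1B, CSF1, CSF2, EPHB2, AXL and KDR, while IGFBP5 and IGFBP7 kept their side. The balance of 2-fold genes did reverse, to 178 higher and 520 lower with equal totals and 63 and 550 with centring. No list median outside the central 95%, and no named gene outside the 2-fold rule, changed direction. Protein-coding genes alone, summed symbols and FAM3C were not run, and of the 1799 genes matched in GENCODE 1798 are protein coding. No paired analysis was possible because only means per line were used, and for the same reason no replicate could be left out.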

Other observations

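All tests here were chosen after the data were seen, and for GC content on the blocks and for GC content and length on the lipid genes the prediction was written before the test was run. The gene families were 13 symbol prefixes looked at after the data were seen, and the genes named from them were chosen after their values were seen.

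Of 13 collagen genes 9 were higher in the BRCA1-deficient line, where 53.5% of all listed genes were higher. Their median of 1.25 was at the 99.9th percentile of random lists matched on expression and the 99.7th with GC content. These percentiles, like those of the interleukins below, turn on the size of the differences as well as their direction. COL8A1 had 39.95 against 13.0 FPKM, COL12A1 40.4 against 16.4 and COL7A1, the anchoring fibril collagen, 6.87 against 1.98, while COL4A5 was lower at 3.05 against 10.5. Interleukins and their receptors were higher in 10 of 14 (98.2nd percentile, 99.88th with GC content). Among them were the receptor antagonist IL1RN at 3.52 against 0.177 FPKM and the decoy receptor IL1R2 at 15.4 against 4.87. Some members had been counted above, COL6A1, COL6A2 and COL1A2 with the mesenchymal genes and IL1A, IL1B and IL6 with the inflammatory genes. Zinc finger genes were lower in 30 of 41, at the 1.85th percentile, but at the 33.7th once GC content was matched. All 6 cytosolic ribosomal protein genes in the table were higher, RPL12 at 1332 against 578 FPKM, a lean within the range of GC-matched lists (61.7th percentile). All 3 S100 genes were higher, S100A6 at 493 against 203 FPKM. Percentiles within the range were also found for solute carriers (34 higher, 22 lower), HOX genes (5 and 3), ADAMTS proteases (4 and 4) and serpins (3 and 4), and counts alone for 4 histone genes, all higher, 4 keratins, 3 of them higher, 4 MAGE-A genes, all lower, and 1 kallikrein, higher.

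The lean of lipid and sterol synthesis genes was not accounted for by transcript GC content or length. Its percentile was 99.98 among random lists matched on GC content and 100 among those matched on transcript length. Without genes in same-direction blocks the percentile was also 100, but that run could not lower the list median. The 2 members in blocks, PLIN2 and ABCA1 (log2 differences -1.85 and 0.94), both lie below the median of 1.48. That run therefore decides nothing on location in blocks. BRCA1 status may lie behind the lean, as a hypothesis that no test here addressed. A difference in culture or library between the lines stays open as well, since each line is given as a mean only and was not tested apart from genotype.

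Direction followed transcript GC content. Transcript length was not the whole source, since within every length quintile the share of higher genes was at least 54.5 points larger in the upper GC tercile than in the lower. A GC bias between libraries could give such a trend at every expression level, and the smallest gap within expression quintiles was 56.5 points. It cannot be told apart from an effect of genotype, because library and genotype coincide. BRCA1 status stays open and untested.

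Neighbouring genes shared a direction in long blocks. GC content alone rarely gave a longest run of the observed length: 2 of 1000 shuffles within GC bins reached its 63 genes, with a maximum of 66. That run did not pass the score threshold, so it is not one of the 3 blocks. The blocks hold 52, 33 and 18 genes and were set apart by their score, not by their length. The 3 blocks held 1.71 times as many called genes per annotated protein-coding gene as the rest (95% interval 1.43 to 2.06), and by block the ratio was 2.27 (1.77 to 2.90) for the lower block at the start of chromosome 9, 1.69 (1.23 to 2.33) for that of chromosome 12 and 1.02 (0.653 to 1.58) for the higher block later on chromosome 9. These ratios decide nothing on a copy number difference between the lines, because the blocks are themselves runs of called genes and the called genes per chromosome had been seen before the blocks were defined. No DNA measurement was used here, so copy number and regional differences in expression both stay open.

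On chromosome 18, 45 of 47 genes were lower and 2 higher, where shuffles within GC bins gave a mean of 12.6 higher. These shuffles break the link between neighbours, so no p-value is given for a chromosome. Chromosome 18 also had the most called genes per 100 annotated protein-coding genes, 17.5, and is counted in the rest in the ratios of the blocks. For 40 genes the log2 FPKM ratio departed from the fold in the table by more than 1. Overlap with another gene on the same strand was not clearly more frequent among them (16 of 40 against 528 of 1657, odds ratio 1.43, 95% interval 0.701 to 2.82, Fisher's exact two-sided p = 0.304), which leaves shared reads undecided.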
